A study of Mus musculus with 7 samples.

How the data were processed

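The 7 libraries measured messenger RNA of regulatory T cells sorted from lymph nodes of 3-week-old mice. By titles and source names, 2 numbered control and 3 numbered Id2/Id3 double-knockout (dKO) libraries form the replicated comparison, and 1 control and 1 dKO library without a number form a single pair. The genotype tags of the pair are the reverse of its titles and source names, so these libraries are named as the library labelled control and the library labelled dKO. Per the labels' protocols, complementary DNA was primed with random hexamers and oligo-dT, and the strand was marked with dUTP. Nothing in the labels ties a library to its own animal, so p-values measure the spread between these libraries, which may be technical.

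The authors' deposited table for the replicated comparison has 39179 genes with Ensembl identifiers. Its signal columns hold, per the file headers, the abundance in dKO and in control. The values are fractional, and their smallest steps are those of read counts divided by a size factor per library and averaged over the 3 dKO or 2 control libraries, so they are called scaled counts here. The deposited log2 values are the log2 ratio of these means, dKO over control, and the deposited p-values are given per gene, raw and adjusted. Per the submitters' processing notes, the tools were RSEM and DESeq, without versions, and the build was mm10 (GRCm38). Recomputing the log2 ratio and the Benjamini-Hochberg adjustment from the deposited columns gave the deposited values within rounding, with largest differences of 0.000211 and 0.00124. The table also marks 15458 genes as confounded, and all of these overlap another gene's coordinates in the table. Whether the counting used the strand is not given in the sources used here.

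For the pair, the deposited FPKM values and the deposited p-values and q-values come from Cuffdiff, per the file headers, which tested 1 library against the other for each of 27901 RefSeq transcript entries. Per the submitters' processing notes, TopHat 1.4.0 and Cuffdiff, with its version given as 0.0.6, were used on build mm9. No coordinates of that build are given here, and the tables were never pooled.

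Tests on per-library counts had been planned before the data were examined, but the table holds group means. As planned for that case, the authors' test was used as deposited, with an adjusted p under 0.05, and no test per gene was added. Genes past that threshold are said to have risen or fallen. No SD or standard error is given for these group means. Of the 39179 genes, 31641 had a p. The rule for the genes named was fixed before the data were examined. It takes Id2 and Id3, the 10 genes with the largest rise and the 10 with the largest fall among genes past the threshold with a CPM of 5 or more (scaled counts over their sum), and up to 4 members of each fixed list with the smallest adjusted p (with none past the threshold, the 2 members with the highest mean). Predicted genes were counted and not named, and a few genes that the rule takes are not reported here. The part of the rule that asked for no overlap between libraries could not be applied to group means. Genes named besides these (among them Ctla4, Foxp3, Il2ra, Ikzf2, Bcl6, Pdcd1, Mki67, Nrp1, Cxcr6, Tnfrsf25, Tnfrsf10b, the Y-linked genes, Xist and those of the closing section) were chosen after their values were seen.

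The 32 gene lists held 513 symbols, of which 509 matched the table. The planned set test on library values was replaced by its pre-ranked form, cameraPR in limma 3.58.1 (R 4.3.3). It was run on signed z values from the authors' raw p, limited to 10 in size, over the 15446 genes with a mean of 10 or more, with a preset correlation of 0.01, two-sided and Benjamini-Hochberg adjusted over the lists. A correlation between genes could not be estimated from group means, and 0.05 was tried as a larger preset value. In 50 runs, z values of these 15446 genes were simulated without correlation between genes. Lists shifted by 1 were called in 96% (S phase) and 94% (type I interferon) of runs. Lists shifted by 0.5 were called in 20% (B cell) and 6% (T helper 17), and lists with no shift in 0.381%. That last share does not give the rate of false calls for lists whose members move together.

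In the pair, FPKM was summed over the transcripts of a gene. Of the entries, 453 repeat an accession at another locus, and 26977 (96.7%) matched 1 Ensembl gene. Log2 ratios used a pseudocount of 1 FPKM, which understates the change of low genes, and 8659 genes with 5 or more FPKM in at least 1 library entered. With 1 library per group there is no test of the conditions. A list's median log2 ratio was set against 10000 random lists of the same size matched on mean expression in 20 bins. In simulated lists of 30 genes among these 8659, a shift of 0.5 lay above the 97.5th percentile in 100% of lists, 0.25 in 77.5% and no shift in 0%.

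Because scaled counts of low genes are sums of a few steps, reads per library were recovered for 18307 genes with a control mean of at most 135 and for 13522 genes with a dKO mean of at most 8. Within 0.00012 scaled counts, 100% of them had exactly 1 solution, and simulated reads were recovered in 100% of genes in both groups. For called genes named here, the dKO mean was also divided by each control library's recovered value alone, with the size factors kept. Higher means could not be resolved, so no count test was run on recovered reads. One read was worth 0.777 and 0.915 scaled counts in the control libraries and 1.08, 1.10 and 1.16 in the dKO libraries. Which numbered library each belongs to cannot be read from the table. A floor of 3 reads over a group would be 1.17 scaled counts in control and 1.08 in dKO.

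Near-identical copies were sought with BLAST+ 2.17.0 among transcripts of the GRCm38 annotation, at 97% identity or more over at least 200 nt and 50% of the shorter transcript. In a simulated set of 200 transcripts, copies with 2% of bases changed were found in 100% and copies with 10% changed in 0%. Of the gene identifiers, 37607 were found in that annotation, which may differ from the authors' release. Other computing used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Alternatives were filters on low values, size and p thresholds, removal of overlapping or copied genes, other settings of the list test, and other pseudocounts, filters and centring in the pair.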

Results

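Regulatory T cells, the Foxp3-expressing CD4 T cells that restrain immune responses, were sorted from lymph nodes of 3-week-old C57BL/6 mice and their messenger RNA was sequenced. The series asked how these cells differ when Id2 and Id3, inhibitors of the E protein transcription factors, are deleted by a Cre recombinase expressed from Foxp3. By the genotype labels of the numbered libraries, control mice carried 1 floxed and 1 normal allele of each gene. The replicated comparison had 2 control and 3 dKO libraries, and a single pair had 1 of each. Scaled counts in the authors' deposited table summed to 3.90e+07 in control and 3.99e+07 in dKO. The size factors recovered from low genes were 1.29 and 1.09 in control and 0.929, 0.910 and 0.860 in dKO, so the control libraries were on average 1.32 times deeper. Values of this comparison are the authors' group means, without an SD, and adjusted p-values are the authors' unless a list test is named.

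Id2 fell in dKO and Id3 did not pass the test. In the authors' deposited table, Id2 (ENSMUSG00000020644, chromosome 12, 25093801 to 25096092, GRCm38) had 783 scaled counts in control and 61.1 in dKO, a log2 fold change of -3.68 with an adjusted p of 1.48e-08. Id3 (ENSMUSG00000007872, chromosome 4, 136143497 to 136145755) had 1376 scaled counts in control and 891 in dKO, a log2 fold change of -0.63 with an adjusted p of 0.209, per the authors' deposited table. Which part of each gene was floxed is not given in the sources used here, and a transcript that lacks only the floxed part would still be counted. Within the list of E protein network genes, Lyl1, a basic helix-loop-helix factor, rose by 1.57 and Tcf3, which encodes the E proteins E12 and E47, rose by 0.67 on the log2 scale of the authors' deposited table. That list had 2 members that rose, 1 that fell (Id2) and 8 that did not pass, and the same 2 and 1 when adjusted over the list alone. Its set test gave an adjusted p of 0.533, with a median log2 fold change of 0.30 and a mean of -0.12, which differ in sign.

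Across all genes, dKO and control regulatory T cells differed at 2075 of 31641 genes by the adjusted p of the authors' deposited table, 1068 higher and 1007 lower in dKO. A change of at least 1 on the log2 scale was listed for 834 of these in the authors' deposited table, 420 higher and 414 lower, and among genes with a mean of 10 or more the median of all 15446 was -0.01. Of the genes called, 1935 were protein-coding, 39 pseudogenes, 38 long intergenic RNAs and 28 antisense RNAs in the authors' deposited table. Among called genes with a CPM of 5 or more, the largest rise was in Mzb1 (chromosome 18, 35647266 to 35649367), an endoplasmic reticulum protein of antibody-making cells, from 11.2 to 905 scaled counts in the authors' deposited table (log2 6.34, adjusted p 1.37e-11). Its control mean corresponded to 24 reads in 1 control library and 4 in the other. The ubiquitin ligase gene Cblc rose by 5.17 on the log2 scale, to 434 scaled counts, and Cdh1, which encodes E-cadherin, rose from 30.7 to 754 scaled counts (adjusted p 0.0259), per the authors' deposited table. The corepressor gene Cbfa2t3 rose by 3.76, the lysosomal channel gene Mcoln2 by 3.71, the secreted nuclease gene Dnase1l3 by 3.61, Eaf2 by 3.61, Khdc1a by 3.56, Neo1 by 3.27 and the kappa light chain gene Igkc by 3.26 on the log2 scale of the authors' deposited table. Where control reads could be recovered, the deposited dKO means were also set against each control library alone. Without the control library that held most Y-linked reads, the log2 fold changes were 7.95 for Mzb1, 5.01 for Cbfa2t3, 4.63 for Khdc1a and 4.19 for Neo1. Eaf2 then had 26.5 scaled counts in control in place of 40.1. Without the other control library the log2 fold changes were 5.60 for Mzb1, 3.10 for Cbfa2t3 and 2.96 for Khdc1a.

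Among called genes with a CPM of 5 or more, the largest falls in the authors' deposited table were those of the ribosomal protein gene Rpl3, from 31322 to 225 scaled counts (log2 -7.12), the ribosomal pseudogene Rpl34-ps1, from 13760 to 99.6 (log2 -7.11), and 1 predicted gene, with adjusted p-values listed at 0. Below that level, 10 called genes were listed at 0 in control and 2 at 0 in dKO in the authors' deposited table. Reads of Rpl3 and Rpl34-ps1 are shared with near-identical copies, and the sum of Rpl3 and Rpl3-ps1 was 94259 in control and 92057 in dKO by the authors' deposited table. Ryr2, a calcium release channel gene that overlaps another gene, fell from 2538 to 24.7 scaled counts with an adjusted p of 0.0106 in the authors' deposited table. The interferon-induced apolipoprotein L genes Apol9b and Apol9a, near-identical to each other, fell from 2318 to 145 and from 641 to 40.8 scaled counts, and their sum had a log2 ratio of -3.99 in the authors' deposited table. The sialyltransferase gene St8sia6 (log2 -3.73), Abhd12b (-3.60) and Gpr15 (-3.12), a receptor for homing to the large intestine, also fell in the authors' deposited table.

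**Figure D1:**
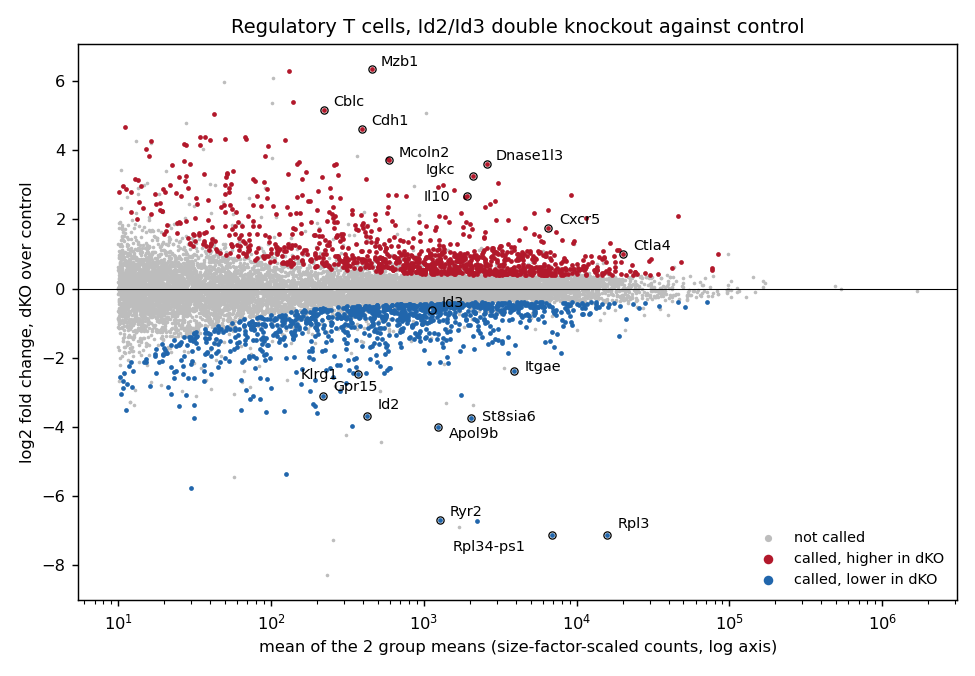
Each point is a gene with a mean of 10 or more, placed by the mean of both group means (scaled counts, log axis) and the log2 fold change of dKO over control, all from the authors' deposited table; red genes were called higher, blue lower and grey not called. Mzb1 lies highest among the labelled genes at 6.34, and Rpl3 and Rpl34-ps1 lie lowest at -7.12 and -7.11.

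Of the genes called, 157 had a near-identical copy with reads, 1899 were searched and had none, and 19 had no transcript sequence to search. Among 70 of the 157 with a change of at least 1, the sum over the gene and its copies moved by less than 0.5 in 18 genes, so their own values are uncertain. Among named genes that overlap another gene were Cbfa2t3, Eaf2, Rpl3, Ryr2, Lyl1, Itgae, Ikzf4, Maf, Itga4, Hif1a, Tpi1, Bcl2, Irf8 and Pim1, and their reads may be shared with that gene. Without any gene that overlaps another, 1238 of 18508 genes passed, 644 higher and 594 lower. Of the recovered control reads of the Y-linked genes Kdm5d and Uty, 601 of 616 (97.6%, exact 95% interval 96.0 to 98.6%, for counting error only) lay in 1 of the 2 control libraries. Counts of called genes without that library cannot be had from group means.

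Cell division genes rose together in dKO. Of 28 genes of G2 and M phase, 26 rose, 0 fell and 2 did not pass in the authors' deposited table, and 28 rose when adjusted over the list alone. The mitotic kinase gene Plk1 rose by 1.07, Nusap1 by 0.99 and the cyclin gene Ccnb2 by 0.97 on the log2 scale, and Birc5 rose from 2027 to 4063 scaled counts, in the authors' deposited table. Mki67, a marker of dividing cells, went from 11467 to 25001 scaled counts with an adjusted p of 0.0495 in the authors' deposited table. Of 27 genes of S phase and DNA replication, 20 rose, 0 fell and 7 did not pass in the authors' deposited table, and 25 rose when adjusted over the list alone. Examples from the authors' deposited table were Cdc45 (log2 0.83), part of the active replicative helicase, Tyms (0.82), which makes thymidylate, Chaf1a (0.77) and Ccne1 (0.77). The set tests of these lists (cameraPR in limma) gave adjusted p-values of 4.39e-24 for G2 and M phase and 1.39e-15 for S phase.

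Glycolysis genes rose as well, with 13 of 18 higher, 0 lower and 5 not passing in the authors' deposited table, and 14 higher when adjusted over the list alone. The lactate transporter gene Slc16a3 rose by 1.39, the hypoxia-inducible factor gene Hif1a by 1.33, Tpi1 by 0.88 and Gapdh by 0.82 on the log2 scale of the authors' deposited table. Gapdh has 36 near-identical copies with reads, and the sum over all of them had a log2 ratio of 0.85. In the unfolded protein response list, 7 of 21 genes rose, 0 fell and 14 did not pass by the authors' deposited table, and 11 rose when adjusted over the list alone. Among them were Asns (log2 1.49), which makes asparagine, Edem1 (0.94) and Sdf2l1 (0.80), which act in the endoplasmic reticulum, and Trib3 (0.89), all from the authors' deposited table. Of 22 genes of T cell receptor signal and immediate early response, 3 rose, 0 fell and 19 did not pass in the authors' deposited table, and 7 rose when adjusted over the list alone. Those were the nuclear receptor genes Nr4a3 (0.79) and Nr4a1 (0.69) and the NF-kappaB inhibitor gene Nfkbia (0.42), on the log2 scale of the authors' deposited table. The set tests (cameraPR in limma) gave adjusted p-values of 2.23e-13 for glycolysis, 4.35e-06 for the unfolded protein response and 0.00439 for T cell receptor signal.

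Type I interferon response genes fell in dKO, 9 of 26 by the authors' deposited table, with 0 that rose and 17 that did not pass, and 17 fell when adjusted over the list alone. Among those that fell in the authors' deposited table were Ifi44 (log2 -3.38), Ifit1 (-1.41), Rtp4 (-0.92) and Xaf1 (-0.77). Of 14 T helper 17 genes, 7 fell, 0 rose and 7 did not pass in the authors' deposited table, and 9 fell when adjusted over the list alone. Il17re, a receptor chain for interleukin 17 family cytokines, had a log2 fold change of -2.81, Il1r1 of -1.74 and the aryl hydrocarbon receptor gene Ahr of -1.31 in the authors' deposited table. The set tests (cameraPR in limma) gave adjusted p-values of 9.89e-09 for type I interferon and 3.47e-06 for T helper 17.

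Lists of FoxO targets, of naive and lymph node homing genes and of chemokine and homing receptors each held more falls than rises. Of 18 FoxO target and PI3K genes, 9 fell, 1 rose and 8 did not pass in the authors' deposited table (10 and 1 when adjusted over the list alone). Of 16 naive and lymph node homing genes, 7 fell, 1 rose and 8 did not pass in the authors' deposited table (11 and 2 when adjusted over the list alone). These lists share S1pr1, which T cells need to leave lymph nodes, from 12490 to 6069 scaled counts (log2 -1.04), the survival cytokine receptor gene Il7r (-0.70) and Klf2 (-0.63), by the authors' deposited table. Sesn1 had a log2 fold change of -1.18, Pik3ip1 of -0.76 and Klf3 of -0.63 in the authors' deposited table. Of 23 chemokine and homing receptor genes, 9 fell, 3 rose and 11 did not pass in the authors' deposited table, and 9 fell and 3 rose when adjusted over the list alone. Gpr15, Itgae (log2 -2.38), which encodes the integrin CD103, and Itga4 (-1.86) fell, while Cxcr5 (1.76), the receptor that guides cells to B cell follicles, and Cxcr3 (1.53) were among those that rose, in the authors' deposited table. The set tests (cameraPR in limma) gave adjusted p-values of 4.46e-06 for FoxO targets, 0.000251 for naive and homing genes and 0.000914 for chemokine receptors. The call for chemokine receptors ended with ranks in place of z (adjusted p 0.103) and without overlapping genes (adjusted p 0.196).

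Genes of regulatory T cell identity moved both ways. Of 19, 4 fell, 2 rose and 13 did not pass in the authors' deposited table, and 8 fell and 2 rose when adjusted over the list alone. The falls in the authors' deposited table were in Itgae, Nt5e (log2 -1.70), which encodes the ectoenzyme CD73, Nrp1 (-1.32) and Ikzf4 (-1.26), and the rises were in the inhibitory receptor genes Tigit (1.01) and Ctla4 (1.01). Foxp3 had 13481 scaled counts in control and 10942 in dKO (adjusted p 0.188) in the authors' deposited table. There, Il2ra and Ikzf2 had log2 fold changes of -0.01 and -0.31. None of these 3 passed with the adjustment over all genes in the authors' deposited table. Their unadjusted p-values there (DESeq) were 0.0188 for Foxp3 and 0.0117 for Ikzf2, both lower in dKO, and 0.977 for Il2ra. The set test (cameraPR in limma) called the list lower with an adjusted p of 0.00984. That call ended with a preset correlation of 0.05 (adjusted p 0.0566), with ranks (0.174) and without overlapping genes (0.650).

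Effector and helper programmes were split. Of 23 effector regulatory T cell genes, 2 rose and 3 fell in the authors' deposited table: the cytokine gene Il10 rose from 517 to 3311 scaled counts (log2 2.68, adjusted p 4.76e-07) and Prdm1 rose by 0.80, while Klrg1 (-2.46), Cxcr6 (579 to 145 scaled counts) and the interleukin 33 receptor gene Il1rl1 (-1.57) fell. Of 20 follicular helper and follicular regulatory genes, 3 rose and 5 fell in the authors' deposited table, with Cxcr5 going from 2967 to 10018 scaled counts (adjusted p 0.0007) and with Maf at -0.90, Pou2af1 at -0.76 and Angptl2 at -0.54 on the log2 scale. Bcl6 and Pdcd1, also linked to follicular T cells, had log2 fold changes of -0.37 and 0.02 and did not pass in the authors' deposited table. Of 12 T helper 1 genes, 3 rose and 0 fell in the authors' deposited table, among them Cxcr3 and Il12rb1 (0.90). Of 14 T helper 2 genes in the authors' deposited table, 1 rose, Pparg (2.17, or 2.85 without the control library that held most Y-linked reads), and 2 fell, Il1rl1 and Il9r (-0.92). Among 25 cytokine and chemokine genes, Il10 rose and Ccl20 (-3.09), Csf1 (-1.89) and Lta (-1.06) fell in the authors' deposited table. Adjusted over the list alone, 4 rose and 5 fell among effector genes, 3 and 5 among follicular genes, 3 and 1 among T helper 1 genes, 1 and 3 among T helper 2 genes and 1 and 3 among cytokine genes. The set tests (cameraPR in limma) passed for none of these lists, with adjusted p-values of 0.913 for effector, 0.521 for follicular, 0.223 for T helper 1, 0.533 for T helper 2 and 0.436 for cytokine genes. The cytokine list had a median of -0.06 and a mean of 0.01, which differ in sign.

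Survival and signalling lists also held rises and falls without a call for the list. Of 22 apoptosis and survival genes, 5 rose and 3 fell in the authors' deposited table, among them the death-promoting genes Bid (0.92), Bmf (0.85) and Bak1 (0.57) with higher values and, with lower ones, the survival gene Bcl2 (-0.79) and the death receptor genes Tnfrsf25 (-1.39) and Tnfrsf10b (-0.74). Of 16 p53 targets, Cdkn1a (1.84), an inhibitor of the cell cycle, and Gtse1 (adjusted p 2.77e-08) rose and Sesn1 fell in the authors' deposited table. Of 18 genes of the T cell receptor complex, 3 rose and 3 fell in the authors' deposited table, including Cd247 (0.58) and, lower, Themis (-0.75), Trat1 (-0.51) and Prkcq (-0.42). Of 17 interleukin 2 and STAT5 genes, 2 rose and 3 fell, with Pim1 at 0.91 and Cish at -0.61 in the authors' deposited table, and of 19 cholesterol synthesis genes Mvd rose (0.65). Adjusted over the list alone, 6 rose and 5 fell among apoptosis genes, 3 and 2 among p53 targets, 4 and 3 in the receptor complex, 3 and 3 among STAT5 genes and 1 and 0 in cholesterol synthesis. The set tests (cameraPR in limma) gave adjusted p-values of 0.315, 0.436, 0.533, 0.917 and 0.315 in that order.

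**Figure D2:**
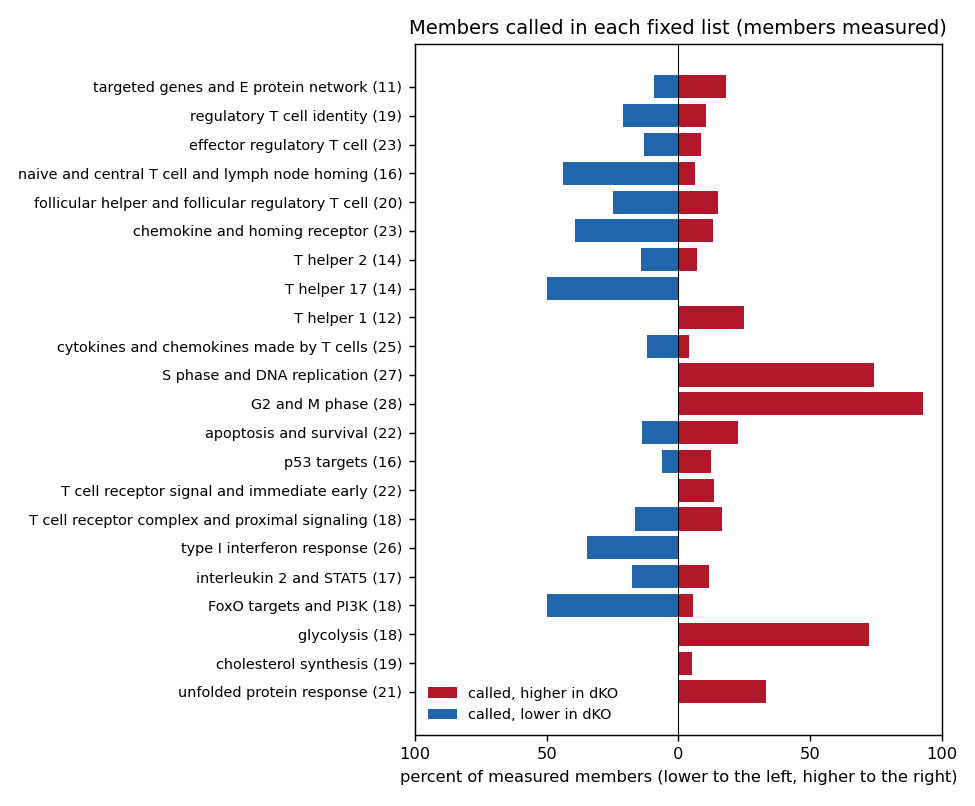
Bars give, for each fixed list of T cell and pathway genes (measured members in parentheses), the percent of members called higher in dKO to the right (red) and lower to the left (blue), by the adjusted p of the authors' deposited table. The longest bars to the right are those of G2 and M phase (26 of 28), S phase (20 of 27) and glycolysis (13 of 18), and the longest to the left are those of T helper 17 (7 of 14) and FoxO targets (9 of 18).

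In the replicated comparison, no list of markers of another cell type was called higher except that of granulocytes and mast cells, on 2 tested genes. Of 18 B cell markers, 0 rose and 1 fell, Cd83 (-0.97), in the authors' deposited table. Of 9 plasma cell markers, Mzb1 rose and Pou2af1 fell, in the authors' deposited table. Of 18 myeloid markers, Ctss fell (-0.68) in the authors' deposited table. Of 15 dendritic cell markers, Irf8 rose (1.63) and Xcr1 (-1.82) and Ccr7 (-0.44) fell, in the authors' deposited table. None of 15 CD8 T and NK cell markers passed in the authors' deposited table (DESeq, 2 with an unadjusted p under 0.05), where Gzma had 59.6 scaled counts in control and 2006 in dKO (adjusted p 0.126) and Cd8b1 a log2 fold change of 0.05. Of 14 immature thymocyte markers, Dntt (3.10) and Mns1 (1.71) rose and 2 fell, among them Themis, in the authors' deposited table. Of 17 stromal and epithelial markers, Epcam (1.92) rose and Col1a2 (-2.08) fell, in the authors' deposited table. None of 9 erythroid markers passed (DESeq, 0 with an unadjusted p under 0.05), with Car2 at -0.04 and Alas2 at -0.01 on the log2 scale of the authors' deposited table, and too few were measured for a set test. Of 17 granulocyte and mast cell markers, Prg2 rose, from 2.47 to 81.7 scaled counts, in the authors' deposited table. Of 8 gamma-delta T cell markers, 2 fell, among them Maf, in the authors' deposited table. Adjusted over the list alone, the counts that rose and fell were 0 and 1 for B cell, 1 and 2 for plasma cell, 0 and 1 for myeloid, 1 and 3 for dendritic cell, 0 and 0 for CD8 T and NK cell and for erythroid, 2 and 2 for thymocyte, 1 and 2 for stromal, 1 and 0 for granulocyte and 0 and 2 for gamma-delta markers. The set tests (cameraPR in limma) gave adjusted p-values of 0.860 for B cell, 0.917 for plasma cell, 0.647 for myeloid, 0.663 for dendritic cell, 0.877 for CD8 T and NK cell, 0.521 for thymocyte and 0.70 for stromal markers. Medians and means differed in sign for plasma cell (-0.21 and 0.76) and dendritic cell markers (-0.04 and 0.03), and the B cell test pointed down with a median of 0.23 and a mean of 0.08. The granulocyte list was called higher (adjusted p 0.00439), which ended without the filter on low genes (0.606), and the gamma-delta list lower (0.00796), which ended without overlapping genes (0.524).

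The single pair showed most of the same directions. In the library labelled dKO, Cxcr5 had 119 FPKM against 35.9 in the library labelled control, Il10 66.5 against 11.8, Mzb1 53.8 against 0.676, Dnase1l3 49.8 against 1.61 and Cxcr3 89.6 against 35.1, by the authors' deposited table. Lower in the library labelled dKO were Klrg1, at 4.97 against 18.2 FPKM, St8sia6, at 2.15 against 20.5, and S1pr1, at 86.0 against 189, by the authors' deposited table. Id2 had 9.69 FPKM in the library labelled dKO and 18.6 in the library labelled control, while Id3 had 221 and 160, by the authors' deposited table. Because the genotype tags of the pair are reversed, each direction here rests on titles and source names. The pair also differed in Y-linked and X-inactivation RNA, with Kdm5d at 4.91 FPKM in the library labelled control and listed at 0 in the other, and Xist at 0.0323 and 29.0, by the authors' deposited table.

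Of 1272 genes called in the replicated comparison and measured in the pair, 1173 (92.2%) had the same direction, against 67.1% of 7321 genes not called. By the genotype tags of the pair in place of its titles, this share of called genes would be 7.78% and Pearson's r -0.81. Whether the pair came from the same animals as any numbered library is not given in the sources used here, so this share may not be independent of the replicated comparison. By titles, Y-linked RNA was higher in control in both comparisons, so the share does not separate genotype from sex. Across these called genes, which are not independent replicates, Pearson's r was 0.81 and Spearman's rho 0.83. Genes called higher had a median log2 ratio of 0.57 in the pair, at percentile 100 of random lists (-0.03 to 0.04), and genes called lower one of -0.60, at percentile 0 (-0.05 to 0.03). Of the fixed lists, all 27 measured genes of G2 and M phase and all 27 of S phase were higher in the library labelled dKO, with medians of 0.69 and 0.44 at percentile 100. Glycolysis genes had a median of 0.46 (percentile 99.98), interferon genes -0.47 and FoxO targets -0.46 (both percentile 0). Regulatory T cell identity genes had a median of -0.41 and chemokine receptors one of -0.42 (both percentile 0.01), and naive and homing genes one of -0.33 (percentile 0.1). The E protein network list, which includes Id2 and Id3 and was not called in the replicated comparison, had a median of 0.56 over 6 genes (percentile 99.8). Of these, 4 were higher, among them Lyl1 (1.62) and the targeted gene Id3 (0.47), while Id2 (-0.87) and Tcf3 (-0.24) were lower. The lists of T cell receptor signal (0.02, percentile 46.3), the unfolded protein response (0.13, percentile 84.4) and T helper 17 (-0.34, percentile 6.84) did not stand apart from random lists. Follicular genes, which had more falls than rises in the replicated comparison, had a median of 0.30 (percentile 99.5, 10 of 16 higher), and the 3 myeloid markers measured had one of 0.59 (percentile 98.5, 2 of 3 higher). Il7r, called lower in the replicated comparison, had 39.5 FPKM in the library labelled dKO against 22.2, and Nr4a3, called higher, 7.57 against 19.3, by the authors' deposited table. Nr4a1, also called higher, had 85.1 FPKM against 118, while Nfkbia, the other called gene of T cell receptor signal, had 511 against 263. Rpl3 had 132 FPKM in the library labelled dKO and 58.9 in the library labelled control, Rpl34-ps1 915 and 336, and Ryr2 3.66 and 2.19, by the authors' deposited table. The 5 highest ratios belonged to the small RNAs Snord37, Snord99, Snord91a, Snora20 and Snord16a and the 5 lowest to Scarna17, Snord65, Mir194-1, Snord53 and Mir23a, each listed at 0 in 1 library of the authors' deposited table. Cuffdiff's test, which compares these libraries and not the conditions, gave 23 transcripts past its threshold in the authors' deposited table, 18 higher and 5 lower in the library labelled dKO, among 13193 tested.

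**Figure D3:**
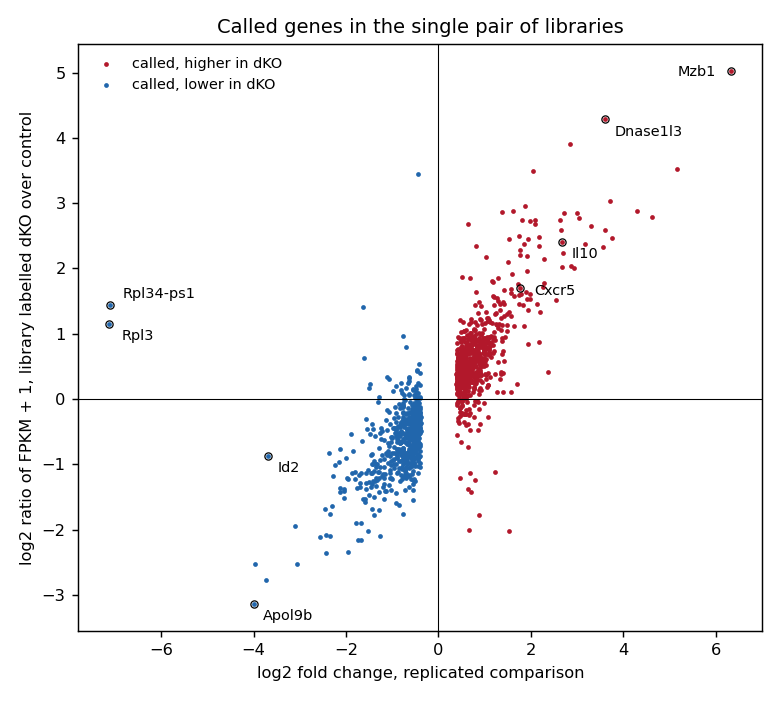
Each point is a gene called in the replicated comparison with 5 or more FPKM in the pair, placed by its log2 fold change there (x axis, from the authors' deposited table) and by the log2 ratio of FPKM + 1 in the library labelled dKO over the library labelled control (y axis); red genes were called higher and blue lower. Of 1272 genes, 1173 lie in the lower left or upper right, and Rpl3 and Rpl34-ps1 lie apart at the upper left.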

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

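Besides the planned size threshold, filters on low values and the settings of the pair, the alternatives here were chosen after the data were seen. Of 31641 genes, 2075 passed as deposited, 2071 with the adjustment recomputed, 1890 of 10004 with a CPM of 5 or more, 2505 of 15446 with a mean of 10 or more, 2117 of protein-coding genes, 1433 at an adjusted p under 0.01 and 2531 under 0.1. With a change of at least 1 on the log2 scale 834 passed, a smaller number by construction, and without overlapping genes 1238 did, where fewer genes were tested. Adjusted p-values of lists that lost their call were 0.0566 for regulatory T cell identity with a preset correlation of 0.05; 0.174 for that list, 0.103 for chemokine and homing receptors and 0.422 for granulocyte and mast cell markers with ranks in place of z; 0.650, 0.196 and, for gamma-delta T cell markers, 0.524 without overlapping genes; and 0.606 for granulocyte and mast cell markers without the filter on low genes. The cause was not tested. No called list reversed its direction. More genes were higher than lower in dKO as deposited (1068 and 1007), and this order turned at an unadjusted p under 0.05, where 4264 passed, 2089 higher and 2175 lower. Of 98 named genes called besides Id2 and Id3, the call held for 98 of 98 tested with a mean of 10 or more and with no filter, 96 of 96 among protein-coding genes, 90 of 90 with a CPM of 5 or more and 68 of 68 without overlapping genes. Of the 98, 58 were tested in each of these settings, and 44 had a change under 1 on the log2 scale. These settings re-adjusted the same raw p-values, and most of these genes were named for a small adjusted p or a large called change. That their calls held was thus largely fixed beforehand. In the pair, 90.4% to 93.0% of called genes had the same direction under other pseudocounts, filters and centring, with medians of 0.38 to 0.61 for genes called higher and -0.64 to -0.37 for genes called lower. By the genotype tags in place of titles, these shares would be 7.79% for genes called higher and 7.77% for genes called lower, and the medians -0.57 and 0.60, since the tags turn each ratio. For 18 called genes with recovered control reads, the fold moved by over 1.5 times in 9 without the control library that held most Y-linked reads and in 6 without the other, and 0 changed sign. Leaving out 1 of the averaged control libraries can lower a rise by at most 1 on the log2 scale. The smallest rise among these genes was 2.17 (Pparg), so no gene that rose could have changed sign. A rise can grow without that limit, so the counts of 9 and 6 are not alike. No paired analysis was possible because the deposited columns are group means without replicate numbers. For the same reason other size factors, other count models, limma on library values, leaving out each library in a test, the replicate block, a pseudocount on library values, fry and an estimated correlation were not run. Depth limits the low genes: 1 read was worth 0.777 to 1.16 scaled counts.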

Other observations

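Chosen only after results were seen were the rule for abundant genes, the counts near Id2, the comparison between the control libraries and the folds against each of them alone, the use of the pair's genotype tags, the need for the ratio of sex chromosomes to pass a test, and the tests of B cell markers, variable-region sums, copy sums and the split of Y-linked reads. With a mean of 1000 or more and a log2 change of at least 2, 28 genes outside the lists were called in the authors' deposited table, 18 higher and 10 lower in dKO. Of the lower, Rpl3, Rpl34-ps1 and 1 predicted gene had log2 ratios of -0.03, -0.15 and -0.26 when summed with their near-identical copies. The tubulin genes Tubb2b and Tubb2a rose by 3.05 and 2.72, the latter from 2420 to 15925 scaled counts, in the authors' deposited table. Also higher there were Slc16a5 (2.99), Tm6sf1 (2.93), Faim3 (2.85), the Wnt ligand gene Wnt10a (2.66), the ceramide synthase gene Cers6 (2.54), Colq (2.37), Igsf23 (2.29), the semaphorin receptor gene Plxnd1 (2.18) and the galectin gene Lgals3 (2.09), on the log2 scale of the authors' deposited table. Lower were the cathepsin gene Ctsw (-3.06), the receptor kinase gene Axl (-2.16), Gsta4 (-2.14) and Spock2 (-2.13) in the authors' deposited table.

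Near Id2, 11 of 32 genes within 5 Mb were called (34.4%) against 13.2% elsewhere (Fisher's exact test, two-sided, p 0.00195, adjusted over 3 regions 0.00586). Near Id3 the count was 23 of 155 (14.8% against 13.3%, p 0.552, adjusted 0.552). The control libraries, told apart by their recovered reads, differed at the genes that were called. Among 208 genes called higher with recovered reads and a control mean of 10 or more, 141 (67.8%) were higher in the control library with Y-linked reads, with a median log2 ratio between the control libraries of 0.31 (percentile 100 of 10000 random lists matched on the control mean, -0.12 to 0.05). Among 185 called lower, 58 (31.4%) were higher in it, with a median of -0.18 (percentile 0.01, -0.11 to 0.04), and among 4482 not called 47.1% were. Cbfa2t3 had 164 reads in that library and 37 in the other, Neo1 98 and 30 and Gzma 118 and 30, whereas Cdh1 had 40 and 33.

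Beside Mzb1, the constant-region genes Ighm and Igkc rose, from 17317 to 74808 and from 394 to 3772 scaled counts, while Igha had 507 in control and 69.0 in dKO (adjusted p 0.251), in the authors' deposited table. RNA of B cells or plasma cells was argued against by 18 of their markers other than Mzb1, whose median log2 fold change was -0.022 (quartiles -0.64 and 0.48), with Cd74 at 2803 in control and 1782 in dKO and Cd79a at 71.2 and 51.1 in the authors' deposited table, and the sort on T cell receptor would also remove such cells. Whether read assignment differed between the replicated groups is not settled by the pair, which has 1 library per group. There Mzb1 had a log2 ratio of 5.03 by titles, above the bound set beforehand against that explanation, and -5.03 by the genotype tags. Titles put 92.2% of called genes in the same direction as the replicated comparison, and the tags 7.78%. Values of 218 variable-region genes summed to 189 in control and 93.0 in dKO, or 1.07% and 0.118% of Ighm and Igkc, so transcripts of unrearranged loci are a candidate source in both groups, and this share alone does not mark the rise in dKO. Ighj1 (9.79 to 91.1, with 24 and 1 control reads) and Adam6b (22.3 to 284, with 48 and 8), which lie in the heavy chain locus, rose in the authors' deposited table, with log2 fold changes of 2.29 and 2.93 against the control library with Y-linked reads alone and, for Adam6b, 5.28 against the other; a difference between the genotypes in the T cells themselves stays open and was not tested.

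Rpl3 and Rpl34-ps1 were over 100 times lower in dKO. Rpl3-ps1 is 99.8% identical to Rpl3 over 1210 nt, and the log2 ratio of their sum was -0.034, where -0.58 would be left if the Rpl3 reads were lost, so reads assigned to a near-identical copy in 1 group may account for the fall. Likewise Rpl34-ps1 and Rpl34 summed to 25687 in control and 23190 in dKO in the authors' deposited table. This is a log2 ratio of -0.15, where -1.11 would be left if the Rpl34-ps1 reads were lost. A loss with an unchanged copy was argued against for both genes by these sums, and Rpl3-ps1 (log2 0.55) and Rpl34 (0.95) were themselves called higher. Loss of the Rpl3 transcript offset by a rise of its copy stays open. In the pair Rpl3 had a log2 ratio of 1.15 by titles, opposite to a loss, and of -1.15 by the genotype tags. Both lay outside the range of 0.5 around 0 set beforehand. Titles put 92.2% of called genes in the same direction as the replicated comparison, and the tags 7.78%. The log2 fold changes of genes with a mean of 10000 or more had an SD of 0.45. That SD is a spread between genes and includes Rpl3 itself, so it does not measure the error of a sum.

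Y-linked genes had higher values in control, with Eif2s3y at 508 and 3.30 scaled counts and Kdm5d at 112 and 2.56, while the X-inactivation RNA Xist had 19641 and 17062, in the authors' deposited table, and none of these passed. Male RNA in 1 control library is the candidate source, since 97.6% of the control reads of Kdm5d and Uty lay there. A male animal as the only source of that library was argued against, because the ratio of a Y-linked gene to its X-linked partner was, as a median over 4 genes, 18.0% of that in the library labelled control of the pair (16.4% for Kdm5d, 19.7% for Uty, 21.1% for Ddx3y and 0.704% for Eif2s3y, whose partner had only 1.68 FPKM in the pair), with all reads of Ddx3y and Eif2s3y taken to lie in that library and the mean of both control libraries taken for the partner. On X and Y, 10.7% of genes were called against 13.4% on autosomes. That ratio of 0.799 did not pass (Fisher's exact test, two-sided, p 0.0662, adjusted 0.0993), and sex could also change genes on autosomes. As a source of the calls, male RNA in 1 control library would place it farther from dKO than the other. Among low called genes with recovered reads it lay nearer. Of 208 called higher, 67.8% were higher in it, and of 185 called lower, 31.4% were. These values argue against that source for these genes, with 1 library of each kind. For genes with higher means, whether sex was a source of the calls stays open. A mix of animals of both sexes and carry-over from another library also stay open, and no biological explanation was tested.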
